A study of Homo sapiens with 9 samples.

How the data were processed

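The data are RNA sequencing profiles of 9 libraries from WA09 human embryonic stem cells carrying a TPH2-EGFP knock-in, 3 each from Day0, Day21 and Day42 of differentiation. Per the labels' protocols, total RNA was taken up in Trizol and about 10 ng went into each library, made with a NEBNext kit for single cells or low input. The submitters' processing notes name cutadapt 1.9, FastQC and the build GRCh38, with no role or order. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. The deposited table gives a raw count per gene and library, per the file headers and the values, which are whole numbers with different sums per library. It also gives FPKM, length- and depth-scaled fragment values, which the authors computed from a library total that is not given in the sources used here. Groups and replicate numbers come from the labels, and columns were matched to libraries by name, with 0 columns unmatched.

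The table held 34961 genes, all with a symbol, and 1942 symbols stood for more than 1 gene identifier. Of the identifiers, 33890 (96.9%) were found in GENCODE release 29, of which 99.9% lay on the same chromosome and strand and 95.4% lay within the GENCODE span extended by 1000 bases at each end. Total counts per library are given with the results. Counts of 4 occurred 7999 times, against 3658 for 3 and 3700 for 5, a ratio of 2.17 to their mean, and counts of 8 had a ratio of 2.10. Counts therefore pile up at multiples of 4, and a count is not an independent fragment. For this reason the limit that a count of 0 allows was set at 3 such steps, or 12 counts, per library. Folds against a day at 0 in all libraries are lower bounds computed against the mean of this limit over that day's libraries. Limits cover counting error only.

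The test was chosen before the data were examined, as limma on log2(FPKM + 1), or edgeR if the table held raw counts, which it did. Named gene lists, the rule for naming genes and most alternatives were fixed then as well. Genes were kept by filterByExpr, which left 20156, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per day was fitted to all 9 libraries with edgeR 4.0.16 in R 4.3.3 (6 residual degrees of freedom, prior 2.42). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Levels are TMM-scaled CPM, and log2 CPM used a prior count of 2. Figures and preparation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. DESeq2 1.42.0 and limma 3.58.1 with statmod 1.5.0 served as alternatives, and DESeq2 gave no adjusted p for 1468 genes.

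A set of 47 gene lists covered pluripotency, neural and serotonin genes, regional factors, other cell types, metabolism, cell cycle and stress. Lists with at least 5 tested members, 45 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Called members were counted over all genes and adjusted over the list alone. Genes named in the text follow a rule in 4 parts. They are a fixed panel of serotonin, pluripotency and neural genes, then the 6 called genes with the largest change per comparison and direction. These 6 had libraries of the days apart, a mean FPKM of at least 10 on the higher day and a protein-coding symbol. The others are up to 4 members per list, called with the largest change or, where none was called, the most expressed, and the 4 genes per combination with the largest smaller step among those called in both steps. Genes outside it are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

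Genes whose annotated spans overlap another gene model are uncertain, because the counting could divide or share their reads and its strand setting is not given in the sources used here. Among genes named in the text, those that overlap a model on the same strand are APOC1, APOE, CDH1, CDH2, CELF4, COL3A1, DDIT3, DLG4, DNMT1, GATA3, HLA-C, HTR2C, LDHA, MALAT1, NEFL, NEUROD1, NME1-NME2, NME2, NOVA1, RBFOX1, RPL8, RPS19, SOX1, TDGF1, TNNT2, TPH2, TTYH1 and VAMP2. Those that overlap a model on the other strand alone are ACTC1, BGN, CAVIN3, CDKN1A, CHAF1A, COL1A1, CRB3, DBH, DDC, EBF1, ELAVL4, FAS, FEV, GATA2, HES5, HOXD9, KCND2, LHX2, MAP2, NKX2-2, NR2F1, OIP5, OLIG1, OTX2, PAX6, PCSK1, PRPH, PTX3, SLC18A2, SLC6A4, SNAP25, SPC25, SPINT2, SYT1, UTS2 and VIM. Ribosomal protein and metallothionein genes have near-identical copies or paralogs and are uncertain as well. Values of 0 stand for no count in any library named.

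Alternatives were limma on log2(FPKM + 1), with pseudocounts of 0.1 and 0.01, on TPM and on quantile-normalized values, all over genes with an FPKM of at least 1 in 3 libraries. Others were an FPKM of at least 5 in 3 libraries, no filter, median-of-ratios scaling, only the 2 days compared, the replicate number as a block, other spread estimates, other fold thresholds, DESeq2, a count of genes with libraries fully apart and a log2 change of at least 1, and each library left out in turn. Counts divided by 4, voom with sample quality weights and total-count scaling were added after seeing the data. The model was tested on simulated counts for the 20156 genes with 50 genes changed at each size. Of genes changed by a log2 of 1, 2, 4 and 6, edgeR called 0, 0, 18 and 60% for Day21 against Day0, 0, 2, 32 and 42% for Day42 against Day21, and 0, 4, 38 and 48% for Day42 against Day0. It called 0, 1 and 0 unchanged genes. With only the 2 days in the model, Day21 against Day0 gave 6, 64, 94 and 98% and called 8 unchanged genes. Simulated libraries of all days in a fit shared 1 spread per gene. In the data the coefficient of variation between libraries was 0.554 on Day0, 0.420 on Day21 and 1.86 on Day42. The simulation therefore does not show how many unchanged genes are called where days differ in spread. Changed genes were drawn only above a minimum mean count, so these shares do not cover low genes.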

Results

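RNA sequencing measured gene expression in WA09 cells, a human embryonic stem cell line also known as H9, in which the EGFP fluorescent reporter was knocked in at TPH2. Cells were sampled at 3 time points on the way from stem cells to serotonin neurons. Day0 libraries came from embryonic stem cells, Day21 libraries from cells labelled as neural progenitors, and Day42 libraries from cells labelled as TPH2-positive serotonin neurons, with 3 libraries per day. The labels number the libraries of a day as biological replicates without saying whether they came from separate differentiations, so p-values measure the spread between these libraries, which may be technical. They do not say whether or how the Day42 cells were sorted by the reporter, so a change on Day42 could come from a selection of cells as well as from the culture. Total counts were 58526466, 66034630 and 65153273 on Day0, 66317715, 66515692 and 63031962 on Day21, and 59429495, 61073164 and 69658328 on Day42. The table listed 34961 genes, of which 20156 passed the count filter and were tested. Levels are CPM, counts relative to the library total scaled by TMM factors, as mean ± SD over the 3 libraries of a day, and changes are on the log2 scale ± SE. A count of 0 allowed up to 12 counts in a library, a mean limit of 0.227 CPM on Day0, 0.203 on Day21 and 0.146 on Day42, and lower bounds on folds were set against it. Limits cover counting error only.

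Libraries of Day42 held fewer genes than those of the other days. Between 22198 and 24359 genes had a count above 0 on Day0 and between 24581 and 24741 on Day21, against 16077, 17101 and 10797 in replicates 1, 2 and 3 of Day42. Ribosomal protein genes took 9.27 ± 0.916% of counts on Day0, 7.35 ± 0.815% on Day21 and 2.01 ± 0.209% on Day42 (SD, n = 3). Genes of the mitochondrial genome took 8.64 ± 2.25%, 8.57 ± 1.82% and 2.76 ± 0.153%. Across genes, which are not independent replicates, Pearson correlations of log2 CPM were 0.938, 0.941 and 0.920 within Day0 and 0.954, 0.947 and 0.954 within Day21. Within Day42, the correlation was 0.811 between replicates 1 and 2, and 0.668 and 0.666 between these and replicate 3. The coefficient of variation between libraries beyond counting noise was 0.554 on Day0, 0.420 on Day21 and 1.86 on Day42. The leading principal component, with 50.5% of the variance, placed Day42 replicate 3 at 518 and the other two Day42 libraries at 178 and 147, while Day0 and Day21 libraries lay below 0. Equal counts were found in at most 2.55% of genes for any pair of libraries, so no library was a copy of another.

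**Figure D1:**
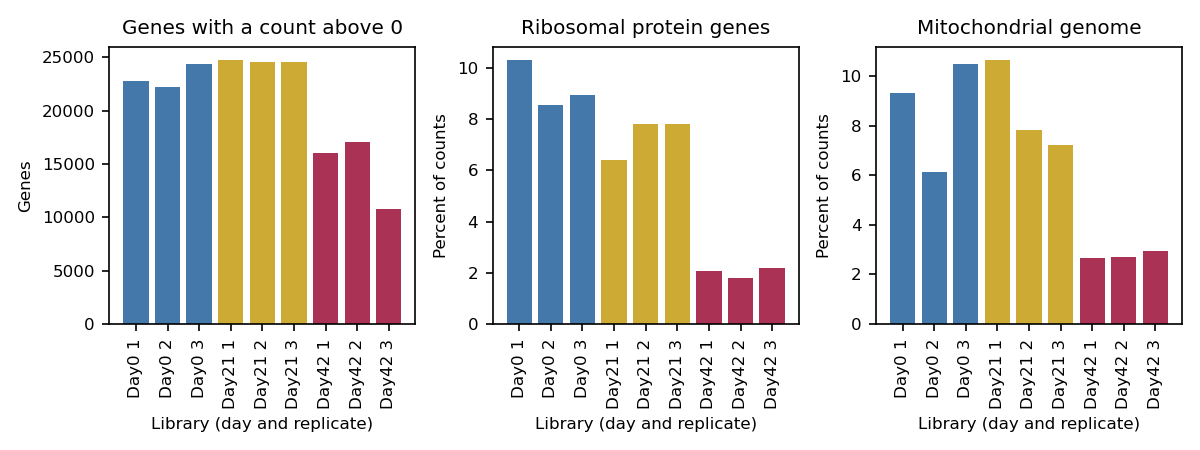
Bars give, for each of the 9 libraries, the number of genes with a count above 0 and the percent of counts from ribosomal protein genes and from the mitochondrial genome, coloured by day. Day42 replicate 3 held 10797 genes, the fewest, and all Day42 libraries had lower ribosomal and mitochondrial shares than any Day0 or Day21 library.

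TPH2 was far higher on Day42 than on the earlier days. TPH2, the neuronal tryptophan hydroxylase that carries out the rate-limiting step of serotonin synthesis (ENSG00000139287, chromosome 12, 71938845 to 72186618 on GRCh38), stood at 1.09 ± 0.614 CPM on Day0, 0.0484 ± 0.0419 CPM on Day21 and 112 ± 22.0 CPM on Day42 (n = 3 each). Its raw counts were 17, 81 and 87 on Day0, 0, 4 and 4 on Day21, and 10730, 8567 and 8258 on Day42. Its Day21 level lay under the limit that a count of 0 allows. It rose by 11.16 ± 1.26 from Day21 to Day42 (edgeR adjusted p = 0.000984) and by 6.68 ± 1.04 from Day0 (edgeR adjusted p = 0.00236). The lower level on Day21 than on Day0 did not pass the test (edgeR adjusted p = 0.0514), though it did in 9 of 26 alternatives (adjusted p from 2.16e-06 to 0.84). FEV, the transcription factor that marks postmitotic serotonin neurons, went from 0.0435 ± 0.0753 CPM to 0.731 ± 0.447 CPM and 561 ± 16.3 CPM, and rose by 9.58 ± 1.19 in the second step (edgeR adjusted p = 0.00142). GATA3, a transcription factor of serotonin neurons, rose by 8.76 ± 0.76 to 163.5 ± 108 CPM (edgeR adjusted p = 0.000352). GATA2, its relative, reached 7.85 ± 10.7 CPM, a mean that rests mostly on Day42 replicate 3, with raw counts of 173, 95 and 1706 in replicates 1, 2 and 3. Its rises from Day21 and Day0 (edgeR adjusted p = 0.05 and 0.0484, the former under the threshold before rounding) were each lost in 12 of 20 alternatives, with adjusted p from 0.000154 to 0.155 and from 0.000302 to 0.142. They were lost without any 1 Day21 library, without Day0 replicate 2 or 3 (and, against Day0, replicate 1), and without Day42 replicate 3, which gave edgeR adjusted p = 0.0912 and 0.101. LMX1B, a serotonin lineage transcription factor, was at 1.21 ± 1.09 CPM on Day42 with counts of 120, 178 and 0, and passed the edgeR test in no comparison (lowest edgeR adjusted p = 0.222). Against Day0 it passed in 1 of 19 alternatives on Day21 and on Day42, voom with sample quality weights (adjusted p = 0.0167 and 0.0116, the highest over alternatives being 1 and 0.529). Reads of TPH2 and GATA3 could be shared with another gene model on the same strand, and those of FEV, GATA2, DDC, SLC18A2, MAP2, PAX6 and NKX2-2 with one on the other strand. This leaves their levels uncertain, since the strand setting of the counting is not given in the sources used here.

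Genes of serotonin handling moved in different directions. DDC, the decarboxylase that completes serotonin synthesis, was at 0 in all Day0 libraries and 6.21 ± 0.486 CPM on Day21, at least 27.3-fold higher (edgeR adjusted p = 0.000431), and rose by 5.74 ± 0.32 further to 332 ± 68.8 CPM on Day42 (edgeR adjusted p = 0.00029). MAOB, a monoamine oxidase, rose by 10.42 ± 0.50 from 0.108 CPM on Day21, under the limit of detection, to 149 ± 29.85 CPM (edgeR adjusted p = 6.14e-05). MAOA, the other monoamine oxidase, fell by 5.84 ± 1.61 from 1.02 ± 0.514 CPM to 0.0157 CPM (edgeR adjusted p = 0.0285), a call lost in 8 of 20 alternatives (adjusted p from 1.52e-06 to 0.112). These include the fits without any 1 Day21 library or Day0 replicate 1 or 2, each with an edgeR adjusted p of at most 0.0795. The change was −8.98 without Day42 replicate 2. SLC18A2, the vesicular monoamine transporter, rose by 9.71 ± 1.82 to 69.6 ± 59.96 CPM (edgeR adjusted p = 0.00565), with raw counts of 7596 and 9399 in replicates 1 and 2 and 65 in replicate 3 of Day42. GCH1, which starts the synthesis of the hydroxylase cofactor, rose by 4.50 ± 0.82 from 1.80 ± 0.122 CPM to 40.7 ± 28.0 CPM (edgeR adjusted p = 0.00519). SLC6A4, the serotonin transporter, had 4 counts in 1 Day0 library, 10 in 1 Day21 library and 0 in the other 7, so it was not detectable at this depth and was not tested. HTR1A, a serotonin autoreceptor, was at 0.704 ± 0.318 CPM on Day0 and at 0 in all Day21 and Day42 libraries, at least 4.83-fold lower on Day42 than on Day0 (edgeR adjusted p = 0.0107).

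**Figure D2:**
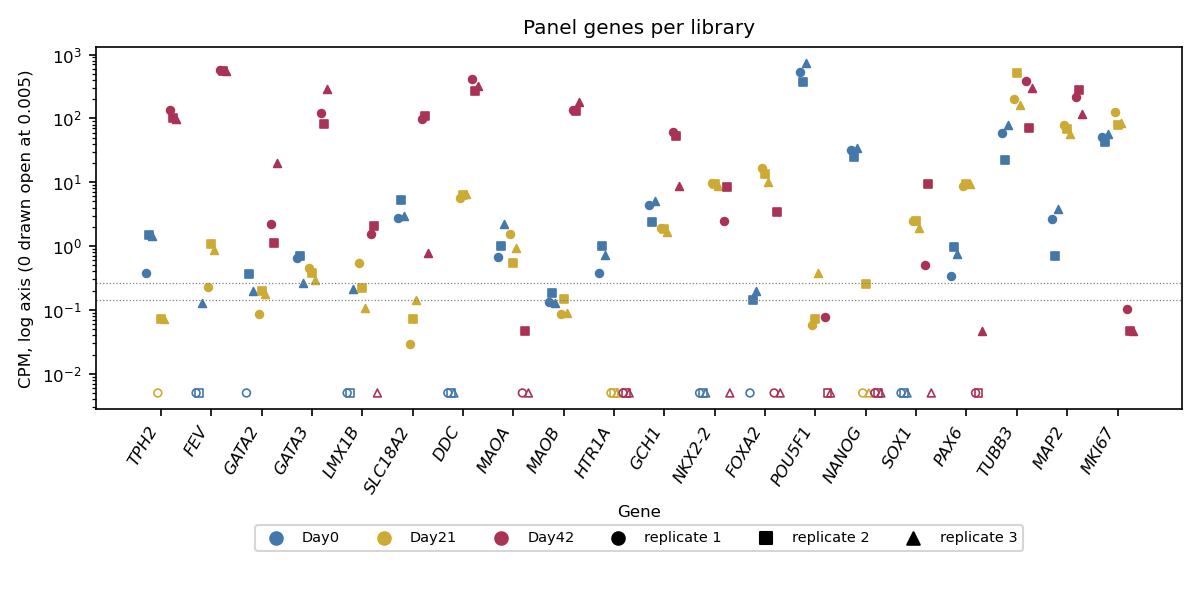
Each point is the CPM of 1 library on a log axis for 20 panel genes, coloured by day and shaped by replicate, with 0 drawn open at the base and dotted lines at the lowest and highest limit that a count of 0 allows. On Day42, TPH2 averaged 112 CPM and FEV 561, while POU5F1, at 542 CPM on Day0, lay below the limit.

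The comparison of Day21 with Day0 asked how the progenitors differed from the stem cells they came from. Pluripotency genes fell and neuronal genes rose. POU5F1, the stem cell factor also called OCT4, fell by 11.64 ± 1.40 from 542 ± 176 CPM to 0.170 ± 0.181 CPM (n = 3 each, edgeR adjusted p = 0.00506), with a change of −12.97 without Day21 replicate 3. STMN2, a tubulin-binding protein of growing neurites, rose by 6.26 ± 0.22 from 2.52 ± 0.213 CPM to 194 ± 1.43 CPM (edgeR adjusted p = 2.25e-05). VIM, the intermediate filament protein of progenitors and mesenchyme, rose by 3.88 ± 0.28 from 64.6 ± 11.6 CPM to 948 ± 134 CPM (edgeR adjusted p = 0.000646). MAP2, a dendritic microtubule protein, rose by 4.84 ± 0.67 from 2.38 ± 1.56 CPM to 68.4 ± 10.7 CPM (edgeR adjusted p = 0.00953). This call was lost in 2 of 26 alternatives, among them without Day0 replicate 1 (edgeR adjusted p = 0.0734, the highest of its alternatives, which went down to 1.08e-11).

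Among called genes with a mean FPKM of at least 10 on the higher day and libraries that did not overlap between days, the largest rises included PLSCR5, a scramblase family member at 0 on Day0 and 66.5 ± 21.9 CPM on Day21. Others were CRYBA1, a lens crystallin at 0 and 29.3 ± 6.99 CPM, and NR2F1, a nuclear receptor of the developing nervous system at 0.0652 CPM and 76.2 ± 26.2 CPM. The collagen gene COL3A1 went from 0.111 CPM to 116 ± 42.8 CPM, and PTX3, a secreted pentraxin, from 0.505 CPM to 155 ± 68.4 CPM. PLSCR5 was at least 293-fold and CRYBA1 at least 129-fold higher. The readthrough gene NME1-NME2 also led this list, and its counts are uncertain because it overlaps NME2. The largest falls included SCGB3A2, a secretoglobin, from 446 ± 158.5 CPM to 0 in all Day21 libraries, at least 2192-fold lower, and GDF3, a stem cell growth factor, from 59.9 ± 10.8 CPM to 0, at least 294.5-fold lower. VRTN, the chemokine CCL26, the polarity gene CRB3 and the metallothionein MT1E, whose reads could be shared with its paralogs, were also among them. VRTN fell from 82.2 ± 62.5 CPM, at least 405-fold or 229-fold without Day0 replicate 3, CCL26 at least 168-fold, CRB3 at least 123-fold and MT1E at least 107-fold. edgeR adjusted p for these 12 genes lay at or below 0.0393.

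Of 20156 genes tested, 266 were higher and 238 lower on Day21 by the edgeR quasi-likelihood test, and 3398 had an unadjusted p under 0.05. In 46.9% of genes the 3 libraries of one day lay outside those of the other, where chance gives 10%, and all 504 called genes were among them. The count depended strongly on which libraries shared the estimate of spread, since 2550 genes were higher and 2459 lower with only the 2 days in the model, and 1434 and 1460 without Day42 replicate 3. Leaving out any 1 Day0 or Day21 library left 91 to 145 genes higher and 42 to 90 lower. Leaving out Day42 replicate 1 gave 387 and 492, leaving out Day42 replicate 2 gave 423 and 561, and DESeq2 called 1389 and 1563.

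Of 25 pluripotency genes, 10 fell, 21 adjusted over the list alone and 24 with only the 2 days in the model (camera adjusted p = 7.3e-26, held with an estimated correlation). Their median change was −8.94, or −6.80 with genes at 0 placed at their bound. TDGF1, a co-receptor of the NODAL pathway, fell from 405 ± 133 CPM to 0.0434 ± 0.0383 CPM, and the zinc finger gene ZSCAN10 from 20.7 ± 12.1 CPM to 0, at least 102-fold or 67.6-fold without Day0 replicate 3. NANOG was at 30.1 ± 4.95 CPM on Day0 and 0.0852 ± 0.1475 CPM on Day21, a difference that did not pass (edgeR adjusted p = 0.0886) but did in 10 of 25 alternatives (adjusted p from 2.36e-06 to 0.303). Genes of the neuronal cytoskeleton and neuronal RNA-binding proteins moved the other way, with 10 of 22 higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 2.4e-11, held with an estimated correlation). DCX, a microtubule protein of migrating neurons, rose from 0.812 ± 0.125 CPM to 59.6 ± 14.3 CPM, and the RNA-binding ELAVL4 from 0.0842 ± 0.0816 CPM to 21.8 ± 1.63 CPM. Of 17 genes of neuronal commitment 2 rose, 9 adjusted over the list alone and 12 with only the 2 days in the model (camera adjusted p = 9.92e-09, held with an estimated correlation). They were NEUROD1, from 0 to 11.5 ± 1.75 CPM, and EBF1, to 11.6 ± 1.74 CPM. Neural progenitor genes had 3 of 22 higher, 4 adjusted over the list alone and 16 with only the 2 days in the model (camera adjusted p = 6.39e-07, held with an estimated correlation). HES5, a Notch target, rose from 0 to 12.2 ± 1.15 CPM and the cadherin CDH2 from 8.56 ± 0.949 CPM to 41.6 ± 8.54 CPM. PAX6 went from 0.682 ± 0.318 CPM to 9.165 ± 0.301 CPM and SOX1 from 0 to 2.29 ± 0.309 CPM, neither past the test (edgeR adjusted p = 0.184 and 0.16). Each passed in 4 of 20 alternatives, with adjusted p from 3.53e-09 to 0.482 for PAX6 and from 8.74e-05 to 0.38 for SOX1. Reads of TDGF1, CDH2, NEUROD1 and SOX1 could be shared with another gene model on the same strand, and those of ELAVL4, EBF1, HES5 and PAX6 with one on the other strand.

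Regional genes of the ventral hindbrain were higher as groups on Day21. Of 14 transcription factors of the serotonin lineage 1 rose, 5 adjusted over the list alone and 8 with only the 2 days in the model (camera adjusted p = 4.85e-05, held with an estimated correlation). EN1, which patterns the midbrain-hindbrain boundary, rose from 0 to 14.4 ± 1.55 CPM, at least 63.4-fold. Of 10 ventral neural tube progenitor genes 1 rose, 7 adjusted over the list alone and 9 with only the 2 days in the model (camera adjusted p = 1.39e-06, held with an estimated correlation), the homeobox gene NKX6-1, from 0 to 4.65 ± 0.826 CPM. edgeR called 0 of 13 floor plate genes over all genes, against 9 higher adjusted over the list alone, 11 with only the 2 days in the model, 10 at an unadjusted p under 0.05 and 10 by DESeq2 (camera adjusted p = 6.18e-07, held with an estimated correlation). SHH, the ligand that patterns the ventral neural tube, was at 0 on Day0 and 40.8 ± 20.9 CPM on Day21 (edgeR adjusted p = 0.0764), FOXA2 at 0.114 and 13.4 ± 3.15 CPM (edgeR adjusted p = 0.258), and NKX2-2 at 0 and 9.19 ± 0.476 CPM (edgeR adjusted p = 0.0888). FOXA2 passed in 7 and NKX2-2 in 8 of 25 alternatives, with adjusted p from 0.000143 to 0.515 and from 1.22e-05 to 0.358. Anterior HOX genes and rhombomere factors also had 0 of 7 called by edgeR, 5 higher adjusted over the list alone, 5 with only the 2 days in the model, 5 at an unadjusted p under 0.05 and 5 by DESeq2 (camera adjusted p = 0.000232, held with an estimated correlation), and HOXA2 was at 0 and 9.69 ± 2.14 CPM (edgeR adjusted p = 0.0692). Of 11 forebrain and midbrain factors 2 fell, with 2 higher and 3 lower adjusted over the list alone. These were OTX2, from 139.6 ± 45.3 CPM to 0.978 ± 0.236 CPM, and HESX1, from 67.9 ± 40.9 CPM to 0.510 ± 0.269 CPM, and the list did not pass camera (adjusted p = 0.985). Hedgehog pathway genes and Wnt targets did not pass camera either (adjusted p = 0.0806 for both), and edgeR called 0 of 13 and 0 of 12, with 2 and 1 higher at an unadjusted p under 0.05, 2 and 1 by DESeq2, and 1 and 0 adjusted over the list alone. With only the 2 days in the model 4 and 3 of them were higher.

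Single genes of neuronal function were called on Day21, while their lists did not pass. SNAP25, a synaptic vesicle fusion protein, rose from 0.414 ± 0.0931 CPM to 9.94 ± 0.887 CPM and VAMP2, a synaptic vesicle protein, from 12.1 ± 1.925 CPM to 63.1 ± 5.85 CPM, the 2 of 23 synaptic genes called (3 adjusted over the list alone). Of 23 ion channel genes 1 rose (3 higher and 1 lower adjusted over the list alone). Of 24 neuropeptide genes 4 rose and 2 fell (8 and 8 adjusted over the list alone), with SST, somatostatin, rising from 2.54 ± 0.869 CPM to 106 ± 20.1 CPM and GAL, galanin, falling from 390.3 ± 79.7 CPM to 18.9 ± 4.87 CPM. Of 20 receptor and scaffold genes 1 rose and 1 fell, with GLRA2 going from 0 to 0.488 ± 0.328 CPM (2 higher and 3 lower adjusted over the list alone). Of 16 genes of serotonin synthesis, transport and breakdown edgeR called DDC over all genes (1 higher and 4 lower adjusted over the list alone and by DESeq2, and 1 and 5 with only the 2 days in the model). None of these lists passed camera (adjusted p = 0.182, 0.61, 0.985, 0.754 and 0.0928). edgeR called 0 of 5 glutamatergic genes, with 0 higher and 1 lower at an unadjusted p under 0.05 and 1 and 0 by DESeq2 (camera adjusted p = 0.809).

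Markers of other cell types were mixed on Day21. Of 16 mesenchymal and fibroblast genes 2 rose, with 6 higher and 2 lower adjusted over the list alone, and 12 and 2 with only the 2 days in the model (camera adjusted p = 0.000369, held with an estimated correlation). These were DCN, an extracellular proteoglycan, from 0.0217 CPM to 90.3 ± 6.35 CPM, and COL3A1. Surface ectoderm and placode genes had 3 of 12 lower, 6 adjusted over the list alone (camera adjusted p = 0.00506, and adjusted p = 0.0628 with an estimated correlation). Among them were the epithelial adhesion genes EPCAM, from 492 ± 60.1 CPM to 2.00 ± 0.220 CPM, and CDH1, from 44.5 ± 5.86 CPM to 0.334 ± 0.179 CPM, both also present in stem cells. Mesoderm and muscle genes had 2 of 7 lower, 3 adjusted over the list alone (camera adjusted p = 0.00315, and adjusted p = 0.158 with an estimated correlation), the cardiac actin ACTC1, from 203 ± 50.9 CPM to 1.49 ± 0.0526 CPM, and TNNT2. Among 8 endoderm genes TTR rose to 21.75 ± 2.88 CPM and AFP fell to 0.690 ± 0.157 CPM (camera adjusted p = 0.985, 2 higher and 2 lower adjusted over the list alone). TTR and OTX2 were also the 1 higher and 1 lower gene among 8 of choroid plexus and ependyma (camera adjusted p = 0.925, 2 and 1 adjusted over the list alone). Among blood and microglia genes AIF1 fell, 1 of 5 (camera adjusted p = 0.235, 1 adjusted over the list alone). edgeR called 0 genes among 15 of astrocytes, 11 of the oligodendrocyte lineage, 11 of neural crest and 8 of endothelium, and camera passed none of these (adjusted p = 0.934, 0.985, 0.324 and 0.427). At an unadjusted p under 0.05 they held 0, 3, 4 and 0 higher and 4, 2, 3 and 1 lower genes, and by DESeq2 0, 3, 2 and 0 higher and 3, 1, 3 and 1 lower. Adjusted over the list alone the counts were 0, 1, 4 and 0 higher and 3, 1, 3 and 0 lower. With only the 2 days in the model they were 4, 4, 6 and 0 higher and 3, 1, 3 and 2 lower. Markers of GABAergic and glycinergic, catecholaminergic, and cholinergic neurons passed camera upward (adjusted p = 0.0121, 0.0485 and 0.0329, lost at adjusted p = 0.346, 0.361 and 0.245 with an estimated correlation). edgeR called 0 of 9, 0 of 7 and 0 of 7, with 2, 3 and 2 higher at an unadjusted p under 0.05, 2, 2 and 2 by DESeq2, and 1, 2 and 2 adjusted over the list alone.

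Genes of cholesterol synthesis fell from Day0 to Day21, 7 of 21, 14 adjusted over the list alone and 13 with only the 2 days in the model, with a median of −1.45 (camera adjusted p = 3.31e-10, held with an estimated correlation). INSIG1, which holds back sterol synthesis, fell from 429.7 ± 39.7 CPM to 68.5 ± 11.035 CPM. Of 19 glycolysis genes 4 fell, also 4 adjusted over the list alone (camera adjusted p = 0.00802, and adjusted p = 0.361 with an estimated correlation), led by LDHA, from 563 ± 83.4 CPM to 64.2 ± 10.2 CPM. Ribosomal protein genes, many of which have processed pseudogenes that could share their reads, passed camera downward with 1 of 25 called, 2 adjusted over the list alone, and a median of −0.46 (camera adjusted p = 0.000314, and adjusted p = 0.548 with an estimated correlation). Of 26 nuclear genes of oxidative phosphorylation 1 fell, CYCS, as many adjusted over the list alone (camera adjusted p = 0.925). edgeR called 0 of 22 mitosis and cell cycle genes, 0 of 24 DNA replication genes and 0 of 13 genes of the mitochondrial genome (camera adjusted p = 0.985, 0.985 and 0.754). They held 1, 1 and 0 higher and 0, 0 and 1 lower genes at an unadjusted p under 0.05, and DESeq2 called 0, 2 and 0 higher and 0, 0 and 0 lower. MKI67, a marker of cycling cells, was at 50.3 ± 7.68 CPM and 95.8 ± 26.3 CPM (edgeR adjusted p = 0.272). Of the 45 lists tested, 17 passed camera, 11 up and 6 down, and 10 did with an estimated correlation. In 13 lists the median, the mean and the direction of the test did not share a sign, none of them past camera, and the median sign of the cell cycle and oxidative phosphorylation lists turned with the scaling. Many list counts of this comparison were larger without Day42 replicate 3, with 23 pluripotency genes lower, and 9 neural progenitor, 7 floor plate and 7 mesenchymal genes higher.

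The comparison of Day42 with Day21 asked how the neurons differed from the progenitors. Lists of serotonin handling, synaptic and neuropeptide genes passed camera upward, and those of the cell cycle, ribosomal proteins and neural progenitors downward. With an estimated correlation, of these 6 the neuropeptide and cell cycle lists held. SNAP25 rose by 6.29 ± 0.27 from 9.94 ± 0.887 CPM to 776 ± 98.8 CPM (n = 3 each, edgeR adjusted p = 3.67e-05). STC1, a secreted glycoprotein hormone, rose by 9.09 ± 0.24 from 5.69 ± 0.317 CPM to 3103.5 ± 191 CPM (edgeR adjusted p = 2.32e-06). MKI67 fell by 10.48 ± 0.59 to 0.0656 ± 0.0318 CPM, under the limit of detection (edgeR adjusted p = 0.0001).

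Besides TPH2 and MAOB, the largest rises by the same rule were those of SLC17A8, a vesicular glutamate transporter, from 0.0182 CPM to 90.1 ± 39.7 CPM, and the neuropeptide gene UTS2, from 0.127 CPM to 136 ± 15.8 CPM. MALL, a membrane proteolipid gene, went from 0 to 40.4 ± 14.9 CPM, at least 199-fold, and CGA, the common subunit of glycoprotein hormones, went from 0.0304 CPM to 32.3 ± 25.5 CPM. The largest falls were BGN, the proteoglycan biglycan, from 127 ± 52.6 CPM to 0 in all Day42 libraries, at least 870.1-fold lower, and PBK, a mitotic kinase, from 109.9 ± 2.04 CPM to 0, at least 754-fold. CHAF1A, SPC25, OLFML3 and OIP5 were at 0 on Day42 and at least 603, 542, 406 and 400.4-fold lower. edgeR adjusted p for these 12 genes lay at or below 0.013. PAX6 fell by 9.01 ± 1.70 to 0.0158 CPM (edgeR adjusted p = 0.00587), under the limit of detection. Its Day42 level rests on 4 counts in replicate 3, without which the fitted change was −12.16. TUBB3, a neuronal tubulin, was at 290.0 ± 189 CPM and 252 ± 162 CPM (edgeR adjusted p = 0.893), and MAP2 at 203 ± 80.5 CPM on Day42 (edgeR adjusted p = 0.0819). MAP2 passed in 12 of 26 alternatives (adjusted p from 0.00215 to 0.227), among them without Day42 replicate 3 (edgeR adjusted p = 0.0349).

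Of 20156 genes tested, 1315 were higher and 3980 lower on Day42 by edgeR, so that 75.2% of calls were lower, against 63.0% (1995 higher, 3396 lower) when libraries were scaled by total count. The share was 45.5% by limma on FPKM and 32.2% after these were rescaled to TPM, both over genes with an FPKM of at least 1 in 3 libraries. The median change of all genes was −0.54 with TMM, −0.51 with median-of-ratios and −0.01 with total-count scaling, so that a gene at −0.54 with TMM changed as much as the middle gene tested. Libraries of the 2 days lay fully apart in 45.8% of genes, where chance gives 10%. Leaving out Day42 replicate 3 gave 2416 higher and 4859 lower genes, leaving out Day21 replicate 1, 2 or 3 gave 761, 621 or 665 higher, and DESeq2 called 2120 higher and 5092 lower. With only the 2 days in the model, where Day0 libraries add nothing to the spread, 1030 were higher and 2878 lower. That fit tested 4649 of the genes called in the main fit and kept 3795 of the calls.

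Neuronal lists had more genes higher than lower. Of 22 genes of the neuronal cytoskeleton and RNA-binding proteins 12 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.07e-10, held with an estimated correlation). STMN4 rose from 53.2 ± 17.1 CPM to 979 ± 91.4 CPM and DCX to 981 ± 109 CPM, while the filament gene PRPH fell from 0.574 ± 0.215 CPM to 0. Of 23 synaptic vesicle and release genes 12 rose, 13 adjusted over the list alone (camera adjusted p = 1.4e-11, and adjusted p = 0.0508 with an estimated correlation). CADPS rose from 2.21 ± 0.443 CPM to 80.5 ± 62.8 CPM and PCLO from 2.84 ± 0.769 CPM to 53.4 ± 13.7 CPM. Of 20 glutamate, GABA and glycine receptor and scaffold genes 8 rose and 1 fell, as many adjusted over the list alone (camera adjusted p = 4.61e-06, and adjusted p = 0.0729 with an estimated correlation). The AMPA receptor subunit GRIA4 went from 2.00 ± 0.595 CPM to 116 ± 36.5 CPM and the scaffold DLG4 from 1.11 ± 0.0440 CPM to 0.0197 CPM. Voltage-gated ion channels had 6 of 23 higher and 5 lower, as many adjusted over the list alone, and 3 lower without Day42 replicate 3 (camera adjusted p = 0.0193, and adjusted p = 0.191 with an estimated correlation). The potassium channel KCND2 was among the former, from 0.234 ± 0.140 CPM to 34.5 ± 15.7 CPM. Neuropeptides, prohormones and their processing enzymes had 13 of 24 higher and 5 lower, as many adjusted over the list alone, with a median of 1.70 and a mean of −0.07 (camera adjusted p = 3.03e-06, held with an estimated correlation). PCSK1, a prohormone convertase, rose from 1.32 ± 0.458 CPM to 519 ± 36.4 CPM, and SST fell from 106 ± 20.1 CPM to 0.0213 CPM. With only the 2 days in the model these lists had, in the order given, 13, 11, 7, 5 and 12 genes higher. They had 1, 0, 1, 2 and 4 lower.

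Of 16 genes of serotonin synthesis, transport and breakdown 7 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 6.41e-05, and adjusted p = 0.0729 with an estimated correlation). Of 14 lineage transcription factors 3 rose and 2 fell, as many adjusted over the list alone, and the list did not pass camera (adjusted p = 0.427). Progenitor lists had more genes lower than higher. Neural progenitor genes had 10 of 22 lower and 1 higher (13 and 1 adjusted over the list alone, camera adjusted p = 0.000378, and adjusted p = 0.159 with an estimated correlation). TTYH1, a membrane channel gene, went from 68.7 ± 29.3 CPM to 0.00785 CPM and HES5 from 12.2 ± 1.15 CPM to 0. Ventral neural tube genes had 6 of 10 lower, with 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.139 with an estimated correlation), such as OLIG1, from 3.09 ± 0.289 CPM to 0. Hedgehog pathway genes had 7 of 13 lower, 8 adjusted over the list alone (camera adjusted p = 0.00254, and adjusted p = 0.191 with an estimated correlation), with GLI2 going from 33.1 ± 15.5 CPM to 0, at least 227-fold. Forebrain and midbrain factors had 7 of 11 lower, as many adjusted over the list alone (camera adjusted p = 0.00913, and adjusted p = 0.0961 with an estimated correlation). Among lists that did not pass camera, 8 of 17 neuronal commitment genes fell (9 adjusted over the list alone), 3 of 13 floor plate genes (3), 3 of 12 Wnt targets (6) and 7 of 25 pluripotency genes (8, and 1 rose). Their camera adjusted p was 0.11, 0.459, 0.197 and 0.638. Of 7 anterior HOX and rhombomere genes 2 rose, EGR2 and PBX3 (camera adjusted p = 0.39), and the sign of the list median turned with the scaling. Without Day42 replicate 3, 1 of these 7 rose. That fit also gave 0 neural progenitor genes higher, 1 ventral neural tube and 1 neuronal commitment gene higher, and 2 pluripotency genes higher and 6 lower. With only the 2 days in the model, serotonin handling genes had 6 higher and 0 lower, lineage factors 2 and 2, and neural progenitor genes 0 and 8. Ventral neural tube, Hedgehog, and forebrain and midbrain genes then had 6, 6 and 5 lower. Neuronal commitment, floor plate and Wnt genes had 6, 3 and 3 lower, pluripotency genes 1 higher and 3 lower, and HOX and rhombomere genes 1 higher.

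Markers of other neuron types and of non-neuronal cells were mostly lower or not past the test on Day42, when libraries also held fewer genes. Of 5 glutamatergic genes 2 rose, SLC17A8 among them, and 2 fell, SLC17A6 and LHX2, to 0 on Day42. GABAergic and glycinergic markers had 2 of 9 lower, catecholaminergic 3 of 7, with DBH going from 1.32 CPM to 0, and cholinergic 3 of 7. Adjusted over the list alone these counts were 2 higher and 3 lower, and 3, 3 and 3 lower. Mesenchymal genes had 4 of 16 lower, as many adjusted over the list alone, with COL1A1 going from 47.9 ± 11.6 CPM to 3.46 ± 1.66 CPM, while DCN stood at 31.2 ± 5.75 CPM on Day42. Astrocyte genes had 1 of 15 higher and 4 lower, oligodendrocyte 3 of 11 lower, neural crest 2 of 11, endoderm 2 of 8, mesoderm 2 of 7 and choroid plexus 3 of 8. Surface ectoderm and placode genes had 4 of 12 higher, GATA3 among them, and 5 lower. edgeR called 0 of 8 endothelial and 0 of 5 blood genes, with 2 and 1 lower and 0 and 1 higher at an unadjusted p under 0.05, and 3 and 1 lower and 0 and 1 higher by DESeq2. Without Day42 replicate 3 the counts were 2 higher and 6 lower for astrocytes and 1 and 4 for the oligodendrocyte lineage. That fit gave 1 lower each for endoderm, endothelial, blood and glutamatergic genes, and 1 catecholaminergic gene higher. None of the lists of other cell types passed camera, with adjusted p from 0.11 to 0.643.

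Genes of the cell cycle fell. Of 22 mitosis and cell cycle genes 17 fell, 19 adjusted over the list alone, with a median of −8.62 or −7.86 with genes at 0 placed at their bound (camera adjusted p = 8.16e-13, held with an estimated correlation). BUB1, a spindle checkpoint kinase, went from 41.3 ± 0.895 CPM to 0 in all Day42 libraries, at least 283-fold lower. DNA replication genes had 10 of 24 lower, 11 adjusted over the list alone and 18 without Day42 replicate 3 (camera adjusted p = 1.81e-05, and adjusted p = 0.173 with an estimated correlation). CDC45 went from 45.3 ± 2.27 CPM to 0.0157 CPM. Of 25 ribosomal protein genes 23 fell, 24 adjusted over the list alone, with a median of −2.35 (camera adjusted p = 1.4e-11, and adjusted p = 0.213 with an estimated correlation). RPS19 fell from 2920.1 ± 691 CPM to 199 ± 43.3 CPM and RPL8 from 3456 ± 225 CPM to 340.0 ± 46.5 CPM. Mitochondrially encoded genes had 8 of 13 lower, 9 adjusted over the list alone (camera adjusted p = 0.00913, and adjusted p = 0.441 with an estimated correlation). The oxidase subunit MT-CO2 went from 42764 ± 9691 CPM to 4441 ± 556 CPM. Of 26 nuclear oxidative phosphorylation genes 12 fell (2 higher and 13 lower adjusted over the list alone, 3 and 7 with total-count scaling, camera adjusted p = 0.111). Of 19 glycolysis genes 3 rose and 5 fell (4 and 7 adjusted over the list alone, 4 and 4 with total-count scaling, camera adjusted p = 0.643). Cholesterol synthesis genes rose, 8 of 21 and as many adjusted over the list alone (7 higher and 2 lower without Day42 replicate 3), with a median of 1.04 (camera adjusted p = 4.3e-09, held with an estimated correlation). INSIG1 went from 68.5 ± 11.035 CPM to 712 ± 96.7 CPM. Of 45 lists, 18 passed camera, 10 up and 8 down, and 4 did with an estimated correlation. In 8 lists the median, the mean and the direction of the test did not share a sign, and of these the neuropeptide list alone passed camera.

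The comparison of Day42 with Day0 set the neurons against the stem cells. DCX, at 0.812 ± 0.125 CPM on Day0, rose by 10.23 ± 0.34 to 981 ± 109 CPM on Day42 (n = 3 each, edgeR adjusted p = 3.33e-06). SCG2, a granin of secretory vesicles, rose by 11.67 ± 0.35 from 0.618 ± 0.180 CPM to 2018 ± 65.4 CPM (edgeR adjusted p = 2.01e-06). DDC was at least 1461-fold higher on Day42 (edgeR adjusted p = 3.82e-05). POU5F1 fell by 14.31 ± 1.55 (edgeR adjusted p = 0.00054, and a change of −18.06 without Day42 replicate 1), and NANOG was at 0 in all Day42 libraries, at least 206.5-fold lower (edgeR adjusted p = 0.00942).

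By the same rule, the other genes with the largest rises were IL13RA2, an interleukin receptor, from 0.0298 CPM to 526 ± 189 CPM, and the glycine receptor subunit GLRA2, from 0 to 47.8 ± 25.3 CPM, at least 210.4-fold. Others were CGA, at least 142-fold or 77.6-fold without Day42 replicate 1, EN1, from 0 to 29.6 ± 17.6 CPM, at least 130.3-fold or 86.6-fold without Day42 replicate 3, and NME1-NME2, whose counts are uncertain. The largest falls were TDGF1, from 405 ± 133 CPM to 0, at least 2779-fold, CAVIN3, a caveolar protein, from 278 ± 69.5 CPM to 0, at least 1906-fold, and MT1G, ACTC1, USP44 and APOC1, at least 1480.0, 1392, 1198 and 1110.0-fold lower. edgeR adjusted p for these and DDC lay at or below 0.00642. FEV rose by 13.49 ± 1.40, GATA3 by 8.24 ± 0.75, MAOB by 9.95 ± 0.49 and GCH1 by 3.37 ± 0.78 (edgeR adjusted p = 0.000458, 0.000263, 3.45e-05 and 0.0115), and MAP2 rose by 6.41 ± 0.72 (edgeR adjusted p = 0.000623). The FEV change was 18.17 without Day0 replicate 3. SLC18A2 rose by 4.25 ± 1.41 and TUBB3 by 2.25 ± 0.74 (edgeR adjusted p = 0.0489 and 0.0474), calls lost in 15 of 20 and 15 of 26 alternatives, with adjusted p from 0.00037 to 0.152 and from 0.0039 to 0.256. SLC18A2 was lost without any 1 library other than Day42 replicate 3 (edgeR adjusted p = 0.00037 without it) and TUBB3 without any other than Day42 replicate 2 (edgeR adjusted p = 0.0148 without it). MAOA fell by 6.20 ± 1.63 and MKI67 by 9.55 ± 0.57 (edgeR adjusted p = 0.02 and 5.91e-05), the MAOA call lost in 4 of 20 alternatives, among them without Day0 replicate 3 (edgeR adjusted p = 0.0575, with 2.04e-07 to 0.0901 over all). The MAOA change was −9.35 without Day42 replicate 2.

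Of 20156 genes tested, 1778 were higher and 4721 lower on Day42 than on Day0 by edgeR, with 72.6% of calls lower, against 60.3% (2561 higher, 3895 lower) with total-count scaling, 47.1% by limma on FPKM and 35.7% by limma on TPM. The median change of all genes was −0.57 with TMM, −0.56 with median-of-ratios and 0.01 with total-count scaling. In 45.5% of genes the libraries lay fully apart, where chance gives 10%. Leaving out Day42 replicate 3 gave 3220 higher and 5664 lower genes, and leaving out Day0 replicate 1 gave 1072 higher. With only the 2 days in the model 1204 were higher and 3229 lower, and 4409 of the 5593 main calls tested there were kept.

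Of 25 pluripotency genes 22 fell, as many adjusted over the list alone, and 11 of them were at 0 in all Day42 libraries (camera adjusted p = 1.24e-10, and adjusted p = 0.0598 with an estimated correlation). Their median change was −12.39, or −7.30 with genes at 0 placed at their bound. Neuronal cytoskeleton and RNA-binding genes had 16 of 22 higher and 1 lower, as many adjusted over the list alone (camera adjusted p = 1.57e-15, held with an estimated correlation). Synaptic genes had 12 of 23 higher, 13 adjusted over the list alone and 18 without Day42 replicate 3 (camera adjusted p = 1.37e-10, held with an estimated correlation), with SYT1 going from 20.1 ± 10.5 CPM to 470.1 ± 64.1 CPM. Receptors had 7 of 20 higher and 2 lower (camera adjusted p = 0.000878, and adjusted p = 0.148 with an estimated correlation). Ion channels had 8 of 23 and 3 (camera adjusted p = 0.0151, and adjusted p = 0.182 with an estimated correlation), and neuropeptides had 10 of 24 and 8, with a median of 1.59 and a mean of −0.06 (camera adjusted p = 0.000512, and adjusted p = 0.0887 with an estimated correlation). Adjusted over the list alone these were 8 and 2, 8 and 4, and 11 and 8. Serotonin handling genes had 7 of 16 higher and 4 lower (camera adjusted p = 0.0205, and adjusted p = 0.185 with an estimated correlation), lineage transcription factors 5 of 14 and 1 (camera adjusted p = 0.000878, and adjusted p = 0.0598 with an estimated correlation), both as many adjusted over the list alone. Floor plate genes had 3 of 13 higher and 2 lower, as many adjusted over the list alone, against 6 and 0 without Day42 replicate 3 and 4 and 0 with total-count scaling (camera adjusted p = 0.0122, and adjusted p = 0.127 with an estimated correlation). Anterior HOX and rhombomere genes had 4 of 7 higher, 5 adjusted over the list alone (camera adjusted p = 0.000625, and adjusted p = 0.0598 with an estimated correlation). With only the 2 days in the model, floor plate genes had 1 higher and 0 lower, lineage transcription factors 3 and 0, and serotonin handling genes 5 and 3. HOX and rhombomere genes had 2 higher in that fit, and synaptic genes 11. Pluripotency genes had 20 lower, and neuronal cytoskeleton and RNA-binding genes 15 higher and 1 lower. Receptors had 6 and 2, ion channels 5 and 2, and neuropeptides 9 and 7.

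Cell cycle genes had 18 of 22 lower, 19 adjusted over the list alone (camera adjusted p = 2.02e-11, held with an estimated correlation). DNA replication genes had 10 of 24 lower, 11 adjusted over the list alone and 17 without Day42 replicate 3 (camera adjusted p = 5.2e-05, and adjusted p = 0.182 with an estimated correlation). All 25 ribosomal protein genes tested fell, over all genes and adjusted over the list alone, with a median of −2.80 (camera adjusted p = 1.37e-12, and adjusted p = 0.185 with an estimated correlation). So did 8 of 13 mitochondrially encoded genes, 9 adjusted over the list alone (camera adjusted p = 0.0148, and adjusted p = 0.47 with an estimated correlation). Surface ectoderm genes had 8 of 12 lower and 1 higher (camera adjusted p = 0.00864, and adjusted p = 0.0953 with an estimated correlation) and mesoderm genes 5 of 7 lower (camera adjusted p = 0.0292, and adjusted p = 0.241 with an estimated correlation), both as many adjusted over the list alone. Of 16 mesenchymal genes 3 rose and 1 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.393), with DCN at 31.2 ± 5.75 CPM and COL3A1 at 54.5 ± 34.5 CPM on Day42. Without Day42 replicate 3 the counts were 4 higher and 2 lower for mesenchymal and 1 and 4 for mesoderm genes. With only the 2 days in the model 16 cell cycle, 8 DNA replication, 25 ribosomal protein and 8 mitochondrially encoded genes were lower. In that fit surface ectoderm genes had 1 higher and 6 lower, mesoderm genes 3 lower, and mesenchymal genes 2 higher and 1 lower. Cholesterol synthesis genes had 2 of 21 higher and 2 lower, as many adjusted over the list alone (camera adjusted p = 0.175), and the sign of their median turned with the scaling. Of 45 lists, 19 passed camera, 12 up and 7 down, and 3 did with an estimated correlation. In 14 lists the median, the mean and the direction of the test did not share a sign, and of these the neuropeptide list alone passed camera.

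**Figure D3:**
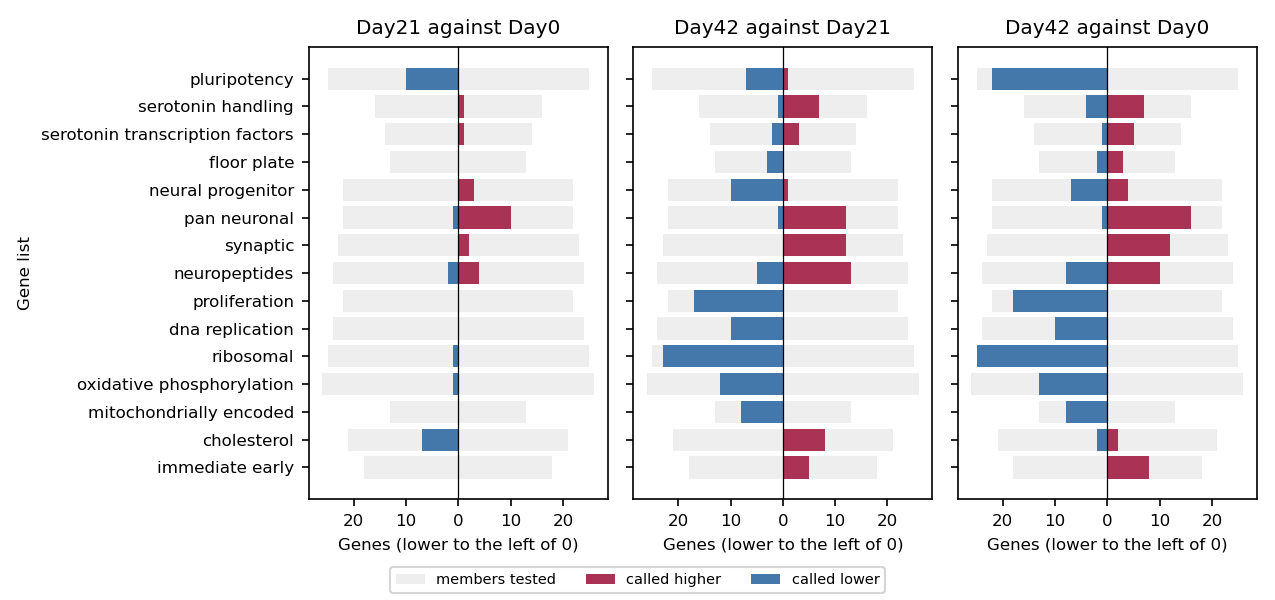
Bars give the number of genes called higher (right of 0) and lower (left of 0) by edgeR in 15 gene lists for the 3 comparisons, over grey bars for the genes tested. Pluripotency genes were lower in 10 and 22 of 25 cases against Day0, and ribosomal protein genes in 23 of 25 from Day21 to Day42.

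Genes called in both steps, Day0 to Day21 and Day21 to Day42, numbered 78 that rose in both, 65 that rose and then fell, 58 that fell in both and 64 that fell and then rose. Simulated groups without change gave 0 in each combination in 20 simulations by edgeR, and independent lists of these sizes would share 17.4, 52.5, 47.0 and 15.5 genes. The simulated groups held no change in either step. They therefore do not give the number of double calls among genes that changed in 1 step. Chance values of the Day21 libraries that both steps share move the steps in opposite directions. Part of the excess of genes that rose and then fell, or fell and then rose, may come from them, since 3 libraries cannot be divided so that each step keeps several of its own. They would lower the other 2 counts. STMN4, a relative of STMN2, went from 1.14 ± 0.223 CPM to 53.2 ± 17.1 CPM and 979 ± 91.4 CPM. STMN2 reached 1827 ± 344 CPM on Day42. The neurofilament gene NEFL went from 27.4 ± 3.74 CPM to 242 ± 50.9 CPM and 1272 ± 61.8 CPM, and VAMP2 from 12.1 ± 1.925 CPM to 63.1 ± 5.85 CPM and 393 ± 56.2 CPM. CRYBA1, PLSCR5, BGN and PTX3 rose and then fell, PTX3 to 1.02 ± 1.51 CPM and CRYBA1 to 0. APOE, an apolipoprotein, fell from 993 ± 459.7 CPM to 41.5 ± 2.96 CPM and 0.0749 CPM. GPATCH4, a nucleolar protein, fell from 365 ± 25.5 CPM to 116 ± 4.75 CPM and 29.3 ± 6.77 CPM, with CAVIN3 and NME2 in the same group. EPCAM fell to 2.00 ± 0.220 CPM and rose to 32.9 ± 13.7 CPM. STC1 fell from 73.2 ± 14.3 CPM to 5.69 ± 0.317 CPM before its rise to 3103.5 ± 191 CPM. SERPINB9, a protease inhibitor, went from 118 ± 80.5 CPM to 1.46 ± 1.14 CPM and 42.1 ± 15.1 CPM, and SPINT2, another protease inhibitor, from 347 ± 39.1 CPM to 14.9 ± 3.44 CPM and 97.7 ± 50.6 CPM. Reads of NEFL, VAMP2, APOE, NME2, COL3A1 and APOC1 could be shared with another gene model on the same strand, and those of BGN, PTX3, CAVIN3 and SPINT2 with one on the other strand. With each step fitted on its own 2 days the counts were 179, 548, 243 and 151, and without Day42 replicate 3 they were 264, 492, 332 and 298.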

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

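Alternatives added after seeing the data were counts divided by 4, voom with sample quality weights, total-count scaling, lists, both steps and single genes with only the 2 days compared, and lists and both steps without Day42 replicate 3. Of the alternative values of the counts of calls, 91 stayed within 1.5 times the main one and 77 did not. For both steps these numbers were 3 and 25, and for counts of lists past camera 17 and 7. Of values for single genes, 4294 kept direction and side of the threshold, 282 fell below it, 89 passed it and 3 reversed. For single lists 747 kept both, 75 fell below and 25 passed it. No gene called was called in the other direction by any alternative run. Among called genes, named or not, the sign of the change turned for 129 from Day21 to Day42 and 74 from Day0 to Day42 with quantile normalization, for 43 and 85 with TPM, and for 1 from Day0 to Day42 without Day0 replicate 3. Single genes were followed for the panel, for the largest changes per comparison and for both steps. Among these the reversed log2 changes, with quantile-normalized log2(FPKM + 1), were 0.33 for TDGF1 and 0.0061 for ACTC1 from Day21 to Day42, and 0.20 for BGN from Day0 to Day42. Genes named only as list members were not followed singly. The cause was not tested here, nor for the counts below, unless stated.

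Counts that moved by over 1.5 times are given as higher and lower, with both steps in the order rose in both, rose then fell, fell in both, fell then rose. limma on log2(FPKM + 1) called 616 and 700 for Day21 against Day0, 2110 and 1759 for Day42 against Day21, and 2079 lower for Day42 against Day0. A pseudocount of 0.1 gave 674 and 651, 2164 and 1896, 2178 lower, and 222, 234, 175 and 130 in both steps. A pseudocount of 0.01 gave 626 and 573, 2080 and 1726, and 1998 lower. TPM gave 594 and 636, 2955 and 1402, 3111 and 1725, 185, 218, 106 and 109 in both steps, and 12 lists for Day42 against Day0. Quantile normalization gave 863 and 834, then 1887 and 2120 lower on Day42 than on Day21 and Day0. It also gave 128 that rose in both steps, 367 that rose then fell, 128 that fell then rose, and 11 lists for Day21 against Day0. With an FPKM of at least 5 in 3 libraries fewer genes were tested, with 431 higher on Day21, and 1022 and 1149 lower on Day42 than on Day21 and Day0. This filter left 162 that rose in both steps, 102 that fell then rose, and 8 and 10 lists against Day0 on Day21 and Day42. These FPKM settings test fewer, more abundant genes, so fewer low genes can be lower.

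Only the 2 days compared gave 2550 and 2459 for Day21 against Day0 and 179, 548, 243 and 151 in both steps, since Day42 libraries then added nothing to the spread in the former. Without an abundance trend, Day21 against Day0 gave 426 and 470. A test against a log2 change of 1 is stricter, with 133 and 105 there and 759 higher from Day21 to Day42. DESeq2 gave 1389 and 1563, and 2120 higher from Day21 to Day42. Libraries fully apart with a log2 change of at least 1, with no test, held for 3802 and 3118 genes, and for 6705 lower from Day21 to Day42. Counts divided by 4 gave 519 and 654, and total-count scaling 548 and 488, with 1995 higher from Day21 to Day42. voom with sample quality weights gave 3734 and 3191, with a weight of 0.0325 for Day42 replicate 3. An estimated correlation left 10, 4 and 3 lists. Leaving out each library gave 91 to 1434 higher and 42 to 1460 lower for Day21 against Day0, 621 to 2416 and 2680 to 5046 for Day42 against Day21, and 1072 to 3220 and 3545 to 5664 for Day42 against Day0. Without Day42 replicate 3, both steps gave 264, 492, 332 and 298, and 16, 19 and 19 lists passed.

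The replicate block gave 76 and 33 for Day21 against Day0, 617 and 1803 for Day42 against Day21, 1051 and 2659 for Day42 against Day0, and 29, 16, 8 and 11 in both steps. For Day42 against Day0 it gave adjusted p = 0.119 for HTR1A and 0.0606 for GCH1, called in all their other alternatives (adjusted p from 0.000156 and 9.79e-06). Deviations from the day mean, correlated across genes for libraries of the same number 1, 2 and 3, were −0.127, 0.0266 and −0.225 between Day0 and Day21. They were −0.00183, −0.0323 and 0.0218 between Day21 and Day42 and −0.00128, −0.0139 and −0.0300 between Day0 and Day42. No pairing by number shows in these values. They do not exclude one, since centring on 3 libraries itself sets the libraries of a day apart. Depth was similar between days, and limits low genes, since a count of 0 allows between 0.141 and 0.269 CPM, depending on the library. The 10797 genes seen in Day42 replicate 3 limit statements on low genes there.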

Other observations

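The choice of scaling as the source of the lower calls, the rankings by Day0 level and with total-count scaling, the comparison of MALAT1 across libraries, and the fit of GC content and length among genes as abundant are tests chosen only after the result was seen. Intervals are bootstraps over genes or exact binomial ones over calls, and do not cover the spread between libraries.

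Immediate early genes, which respond to stimulation and to dissociation of cells, rose from Day21 to Day42, 5 of 18, as many adjusted over the list alone and 10 without Day42 replicate 3 (camera adjusted p = 4.05e-08, and adjusted p = 0.0961 with an estimated correlation). FOS, a transcription factor subunit, went from 4.17 ± 1.27 CPM to 397 ± 39.1 CPM, and EGR1 from 3.21 ± 1.83 CPM to 196 ± 29.7 CPM (edgeR adjusted p = 9.07e-05 and 0.000431). Against Day0, 8 of them rose, 10 adjusted over the list alone and 13 without Day42 replicate 3 (camera adjusted p = 1.57e-07, and adjusted p = 0.105 with an estimated correlation). edgeR called 0 from Day0 to Day21, with 2 higher adjusted over the list alone, 5 higher and 1 lower at an unadjusted p under 0.05 and 4 higher by DESeq2 (camera adjusted p = 0.324). Genes of the unfolded protein and integrated stress response had 4 of 15 higher and 1 lower on Day42 than on Day21, as many adjusted over the list alone, and 3 and 2 without Day42 replicate 3 (camera adjusted p = 0.0307, and adjusted p = 0.139 with an estimated correlation). ATF3, a stress-induced transcription factor, went from 8.71 ± 3.77 CPM to 67.2 ± 33.4 CPM, while SDF2L1, a chaperone cofactor, went from 202 ± 52.2 CPM to 29.7 ± 17.6 CPM. Against Day0, 4 rose and 2 fell, as many adjusted over the list alone (camera adjusted p = 0.0388, and adjusted p = 0.148 with an estimated correlation), and on Day21 edgeR called DDIT3, which rose, 1 of 15 (camera adjusted p = 0.985), from 23.8 ± 7.11 CPM to 97.4 ± 22.1 CPM. Neuronal splicing regulators had 7 of 19 higher and 1 lower from Day21 to Day42, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00228, and adjusted p = 0.0961 with an estimated correlation). CELF4 went from 4.56 ± 0.219 CPM to 109 ± 48.6 CPM and RBFOX1 from 0.520 ± 0.504 CPM to 0. Against Day0, 8 rose and 3 fell, as many adjusted over the list alone (camera adjusted p = 0.00145, and adjusted p = 0.0953 with an estimated correlation), and on Day21 edgeR called NOVA1, which rose to 44.4 ± 5.07 CPM, against 3 higher and 1 lower by DESeq2 and 4 and 3 with only the 2 days in the model (camera adjusted p = 0.752).

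Other lists did not pass camera in any comparison. Of 14 p53 targets and apoptosis genes, CDKN1A, a cell cycle inhibitor, rose from 10.65 ± 4.45 CPM to 319 ± 94.4 CPM (edgeR adjusted p = 0.00199), FAS fell to 0.0171 CPM on Day42 from 9.16 ± 1.18 CPM, and 5 fell there without Day42 replicate 3. Against Day0, 2 rose and 1 fell on Day42, and 3 and 5 without Day42 replicate 3 (camera adjusted p = 0.0619, 0.279 and 0.935 in the 3 comparisons). Of 15 interferon response genes, HLA-C fell from 106 ± 21.6 CPM to 38.7 ± 4.16 CPM, 3 fell from Day21 to Day42, among them ISG15, from 180.5 ± 56.9 CPM to 3.43 ± 3.23 CPM, and 4 fell against Day0 (camera adjusted p = 0.37, 0.459 and 0.918). Of 18 DNA methylation and chromatin regulators edgeR called 0 on Day21, with 1 higher and 2 lower at an unadjusted p under 0.05 and 2 lower by DESeq2. In that list 5 fell from Day21 to Day42 and 3 against Day0 (camera adjusted p = 0.985, 0.459 and 0.523), with DNMT1, the maintenance methyltransferase, going from 229.9 ± 18.2 CPM to 36.7 ± 14.6 CPM. Of 15 hypoxia genes edgeR called 0 on Day21, with 1 higher and 1 lower at an unadjusted p under 0.05 and by DESeq2, and 1 higher and 2 lower on Day42 against either day (camera adjusted p = 0.752, 0.53 and 0.78), where the sign of the list median turned with the scaling. Of 11 stress hormone, oxytocin, opioid and adrenergic receptor genes, OXTR rose to 10.2 ± 4.24 CPM on Day21, CNR1 rose and 3 fell from Day21 to Day42, and 2 rose and 2 fell against Day0 (camera adjusted p = 0.981, 0.459 and 0.508). Counts of these lists adjusted over the list alone differed from those over all genes by at most 1 per direction. Without Day42 replicate 3, 0 interferon genes were higher and 5 lower from Day21 to Day42 and 1 and 6 against Day0, 1 chromatin regulator was higher and 6 lower from Day21 to Day42, 3 chromatin regulators higher and 7 lower against Day0, and 3 and 4 hypoxia genes higher against Day21 and Day0. For Day21 against Day0 that fit gave 3 p53 targets, 2 interferon, 2 hypoxia, 1 chromatin, 3 immediate early and 4 splicing genes higher. In the same order it gave 1, 2, 1, 1, 0 and 1 lower. With only the 2 days in the model 7 p53 targets were higher and 1 lower. Of serotonin receptors other than the autoreceptors 3 were tested, too few for camera. HTR3A went from 16.1 ± 3.16 CPM to 2.72 ± 0.630 CPM and 0, a fall on Day42 (edgeR adjusted p = 0.00142 against Day21), and edgeR did not call HTR2C or HTR7. Of the 3, DESeq2 called 0 higher and 2 lower on Day21 against Day0, 1 and 1 on Day42 against Day21, and 0 and 1 on Day42 against Day0, where edgeR called 2 lower without Day42 replicate 3. Of 27 posterior HOX genes 11 were in the table and 0 passed the count filter, so edgeR, DESeq2 and an unadjusted p gave no result for them. The highest count was 20, in HOXD9.

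More genes were lower than higher on Day42 than on Day21. Whether genes were missed by chance in single Day42 libraries stays open. Of 14147 genes with a mean of at least 1 CPM on Day21, 962 were at 0 in all 3 Day42 libraries. That is 2.901 times (95% interval 2.74 to 3.06) the 332 that independent zeros give in bins of Day21 level. Genes of 1 bin can differ in their Day42 level, and low ones are missed more often in every library. Chance misses alone can therefore exceed the number from independent zeros. Over TMM, median-of-ratios and total-count scaling of the same genes the lowest share of lower calls was 62.99% (61.7 to 64.3), which argues against the choice among these 3 as the whole source, though limma on FPKM and TPM, over more abundant genes, gave 45.5% and 32.2%. Low-abundance genes as the whole source cannot be told apart from a fall at all levels, because the share in the highest of 3 bins of equal size moved with the ranking and the scaling. By mean log2 CPM over all libraries, a ranking in which a fall on Day42 itself moves a gene down, lower calls made up 98.6, 71.1 and 48.02% (45.7 to 50.3) from the low to the high bin. The highest bin held 63.2% (60.9 to 65.4) by Day0 level and 62.8% (60.4 to 65.0) by Day21 level, but 41.9 and 40.6% with total-count scaling, and 45.4% by the higher of the Day21 and Day42 levels. A smaller set of expressed genes on Day42 and a lower yield of rare transcripts in those libraries, where 874 of 903 genes at 0 in exactly 1 library and at 10 CPM or more in both others were at 0 in replicate 3, both stay open.

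Some genes differed at least 16-fold between libraries of the same day on Day0 or Day21, 73 at a mean of at least 10 CPM. MALAT1, a nuclear noncoding RNA chosen after its values were seen, stood at 7256, 5591 and 1.86 CPM on Day0, 172, 30063 and 131 CPM on Day21, and 30560.0, 47146 and 42108 CPM on Day42. Whether the libraries low in MALAT1 share an axis stays open. Deviations of Day0 replicate 3 from its day, correlated across genes, which are not independent replicates, gave 0.301 with those of Day21 replicate 1 and −0.225 with those of Day21 replicate 3. Centring on 3 libraries sets the latter 2 apart (−0.569), so that the sign of either value decides nothing. Reads divided between overlapping gene models may contribute, since 47.9% of the 73 genes overlapped another model on the same strand against 25.9% of genes matched on abundance, a ratio of 1.855 (95% interval 1.21 to 2.93). Real differences between cultures stay open and were not tested.

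Ribosomal protein genes were lower on Day42 than on Day21, with a median of −2.35 on the log2 scale. Loss of short transcripts stays open. The ribosomal median lay −0.9671 (95% interval −1.35 to −0.60) from that of 595 other genes as abundant, at −1.38. These genes were held only to be no longer than the longest transcript of any listed ribosomal gene. That cap kept most of the 670 protein-coding genes as abundant, so it did not match them on length. A single Day42 library is argued against, since at least 21 of 25 were lower without any 1 Day42 library (22, 21 and 25 without replicate 1, 2 and 3). Whether GC content and length together account for the lower ribosomal protein genes stays open, since 2 fits differed. After a fit over all other genes, with an R squared of 0.0654, the median residual was −0.2039 (−0.69 to 0.24). Among 670 protein-coding genes as abundant the residual was −1.027 (−1.17 to −0.31), an interval that crosses the bound of −0.5 set for it, so that GC content and length cannot be told apart from a change in these genes. A lower ribosomal protein output of neurons than of progenitors stays open and was not tested.

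Other splits of the 6 libraries of each comparison number 10 with the real one, too few for a share under 0.05. The real split gave 504, 5295 and 6499 calls for Day21 against Day0, Day42 against Day21 and Day42 against Day0, the highest other split gave 0 in each, and so 1 split of 10 reached the real value. Every other split puts libraries of both days into each group, so that the difference between days counts as spread. Few calls follow from that alone, and the 0 calls of the other splits add no weight to the real ones.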
